A study of Mus musculus with 25 samples.

How the data were processed

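RNA from 25 mouse samples in 10 groups was measured on 25 Affymetrix Mouse 430 2.0 arrays, 1 sample per array. The deposited values were log2 signals per probe set, which the authors computed with RMA; its version was not given in the sources used here. The upper quantiles of the 25 columns nearly matched, as after quantile normalization of probes, and no centring of genes was found. The values ran from 2.05 to 15.11, with column medians between 6.11 and 6.30, and 0 columns were identical. Per the labels, 100 ng of total RNA was amplified and labelled with biotin for every sample. Arrays hold no read counts, so their number limits the precision.

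Probe sets were named from the platform annotation supplied with the values, with symbols looked up through Entrez IDs in the RefSeq table of GRCm38.p6, which changed 0 symbols and did not hold the ID of 204 probe sets. Of 45101 probe sets, 34945 had 1 symbol, 932 had several, 9160 were not listed and 64 were controls. Each of the 18193 genes took the value of its probe set with the highest mean over all 25 arrays, which mattered for the 9010 genes with more than 1 probe set. Probe sets with several symbols or none named no gene.

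The 3 models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The induced macrophage model held 6 arrays with 3 residual degrees of freedom, the liver, colon and iHep model 11 arrays with 6, and the Cdx2 shRNA model 8 arrays with 6. A gene was tested where its probe set lay above the 40th percentile of its array in at least 2 arrays of the model. The threshold was a two-sided Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. Adjustment was over the genes of each of the 10 comparisons separately, not across comparisons. Against a group under the 40th percentile of its arrays (5.52 to 5.80), a fold change is limited by the background of its probe set and is no exact size. Errors of log2 fold changes are limma's standard errors (SE), and errors of group levels are standard deviations (SD). The labels do not say whether replicates came from separate cultures or animals, apart from the iHep lines, which are labelled independent, so the p-values measure only the spread between these samples.

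The groups, comparisons, tests, 27 gene lists and the rule for named genes were set before the data were examined. Named genes were the shRNA targets Ebf1, Pou2af1 and Cdx2 and the transgenes Foxa1 and Hnf4a, the 6 highest and 6 lowest log2 fold changes of a comparison among genes past the threshold whose groups did not overlap, and list members. Clone-style symbols were passed over. From each list, up to 4 members past the threshold and up to 2 not past it were taken by size, and any member of the liver, intestinal and macrophage regulators or B lineage genes. Lists were tested with camera (limma), which compares a list with the other genes, using a correlation between genes estimated from the residuals and adjustment over the lists of a comparison, 170 tests in all. The gene targeted by an shRNA was left out of the lists in its own comparison.

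A tissue axis was built from 1866 genes that passed the threshold between adult liver and colon and differed by at least 3 on the log2 scale. Each array received its median position over these genes, with 0 at the colon mean and 1 at the adult liver mean, and groups were compared by exact two-sided permutation tests. The axis genes were chosen on the liver and colon arrays, so the positions of those 2 groups are fixed by construction.

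Alternatives were no filter, a filter at the 60th percentile, the mean of a gene's probe sets, probe sets shared between transcripts left out, quantile normalization repeated over the arrays of a model, a mean-variance trend with robust fitting, a minimum log2 change of 1, all 25 arrays in 1 model, the replicate number as a block, each array left out in turn, and other list tests. Centring each array on its median and leaving out genes that separated arrays by spike signal were added after seeing the data, as were a permutation of the axis within same-numbered pairs, the axis without those genes and the scramble macrophage arrays divided between the 2 shRNAs. Same-numbered arrays deviated together in the Cdx2 shRNA model, with correlations over genes of 0.53, 0.32, 0.58 and 0.44, so the numbers were taken to pair those arrays, though not every array of replicate 2 correlated best with its own number; the labels do not state the pairing. The models were tested on simulated data made from the observed means and spreads, with 50 changed genes per size. In the simulated Ebf1 comparison of 12379 genes, 62% of changes of 1 and 92% of changes of 2 on the log2 scale were recovered. In the simulated engrafted comparison of 14664 genes the shares were 18% and 72%, and in the simulated Cdx2 comparison of 13656 genes 76% and 92%. Of the genes called in these simulations, 3.6%, 8.91% and 1.96% were unchanged, in the same order. Noise was drawn independently for each gene around a mean common to all groups, so correlation between genes was not simulated.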

Results

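The data were 25 array profiles of engineered and native mouse cells. Induced macrophages (iMac) were made by the authors from a pre-B cell line through a transcription factor switched on with estradiol, and received scramble, Ebf1 or Pou2af1 shRNA (n = 2 arrays per group). Induced hepatocytes (iHep) were made from embryonic fibroblasts with the transgenes Foxa1 and Hnf4a (n = 3), and were compared with fetal liver, adult liver and colon crypts (n = 2 each). Colon-engrafted iHeps (n = 2) were sorted by their green fluorescence from the damaged colon of immunodeficient mice after transplantation. Further iHeps received scramble or Cdx2 shRNA (n = 4 each). The labels of the adult liver arrays conflict, naming whole liver at 8 weeks in one place and hepatocytes isolated with collagenase at 10 weeks in another, so which cells they held was not known. Levels are log2 signals, and the number of arrays limits their precision.

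Ebf1, a transcription factor of early B cells, was at 8.35 ± 0.05 (SD) with scramble shRNA and at 7.31 ± 0.14 with its own shRNA, and fell by 1.04 ± 0.11 (log2 fold change ± SE, adjusted p = 0.00389). Pou2af1, a B cell coactivator, was at 11.30 ± 0.06 in the arrays labelled Pou2af1 shRNA and at 11.16 ± 0.14 with scramble shRNA, and so was not lower under its own shRNA. Pou2af1 rose to 11.91 ± 0.13 with Ebf1 shRNA, by 0.75 ± 0.12 (adjusted p = 0.0138), a call that ended at 0.66 without Ebf1 replicate 1 or without scramble replicate 2. Cdx2, a master regulator of intestinal epithelium, fell from 9.12 ± 0.21 to 7.96 ± 0.12 with Cdx2 shRNA, a change of −1.16 ± 0.12 (adjusted p = 0.00397). The Cdx2 level was 9.49 ± 0.74 in iHep, 5.33 ± 0.50 in fetal liver, 5.88 ± 0.25 in adult liver, 11.07 ± 0.04 in engrafted iHep and 11.66 ± 0.05 in colon. Hnf4a, a nuclear receptor of hepatocytes and gut epithelium, was at 9.64 ± 1.72 in iHep, with 7.67 in replicate 1 and 10.78 and 10.48 in the others. Its level was 8.91 ± 0.75 in fetal liver, 11.93 ± 0.26 in adult liver, 12.13 ± 0.06 in engrafted iHep and 12.69 ± 0.01 in colon. Foxa1, a pioneer factor of endoderm, was at 4.32 ± 0.19 in iHep, 7.64 ± 1.30 in adult liver, 8.82 ± 0.62 in engrafted iHep and 10.23 ± 0.15 in colon. The arrays do not separate transgene from endogenous RNA, and a probe set outside the transgene would not see it.

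**Figure D1:**
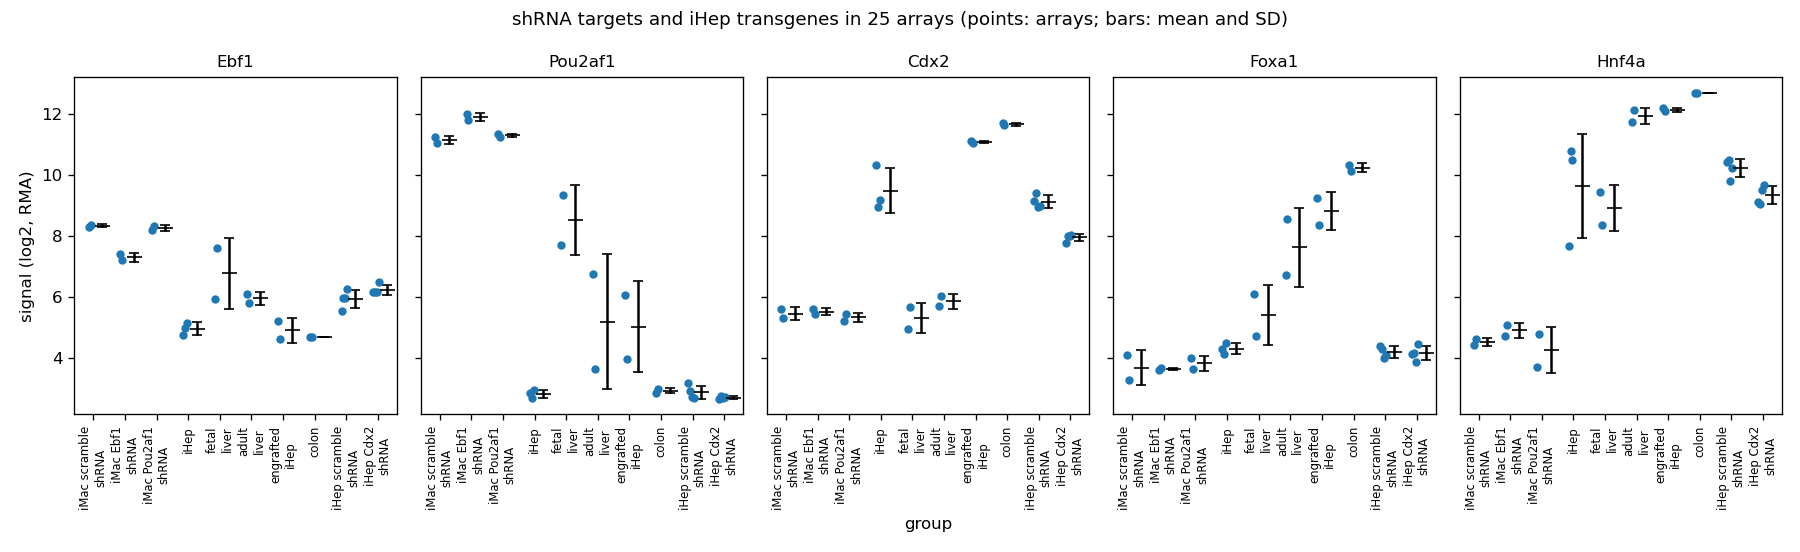
Signal (log2, RMA) of the 3 shRNA targets and the 2 iHep transgenes in each of the 25 arrays by group, with group means and SD. Pou2af1 was at 11.30 under its own shRNA and 11.16 with scramble shRNA, whereas Ebf1 and Cdx2 were lower under theirs.

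With Ebf1 shRNA, induced macrophages carried lower levels of interferon-induced genes and higher levels of inflammatory cytokine genes than with scramble shRNA (n = 2 arrays each). Of 21 interferon response genes, 18 fell over all genes tested and 21 when adjusted over the list alone, with a median log2 fold change of −0.72 (camera adjusted p = 0.036). Among these antiviral genes Ifit3 changed by −1.44 ± 0.13, Ifit2 by −1.24 ± 0.12, Usp18, which restrains interferon signalling, by −1.23 ± 0.10 and Mx2 by −1.15 ± 0.09. Dhx58, at −0.37, and Eif2ak2, at −0.32, were not past the threshold. Of 23 cytokine and chemokine genes, 10 rose and 0 fell, against 13 and 2 adjusted over the list alone, with a median of 0.42 (camera adjusted p = 0.0475). The chemokine genes Ccl4, Cxcl2, Cxcl3 and Ccl7 rose by 3.03 ± 0.13, 2.66 ± 0.09, 2.26 ± 0.13 and 1.71 ± 0.10, whereas Cxcl10 stood at −0.84 and Ccl5 at 0.68, not past it. The highest single increase was Stfa3, a cysteine protease inhibitor of myeloid cells, at 12.96 ± 0.04 (SD) against 6.04 ± 0.11 (adjusted p = 9.2e-05). It was followed by the protocadherin Pcdh9 (4.21 ± 0.15), Mansc1 (3.84 ± 0.25) and the cystine transporter Slc7a11 (3.83 ± 0.24). The myeloid receptor Trem1 and the interleukin 1 family member Il1f9 rose by 3.66 ± 0.13 and 3.56 ± 0.12. The lowest were the interferon-induced GTPase Gbp3 (−2.67 ± 0.12), the microtubule regulator Stmn1 (−2.03 ± 0.19), the AMP kinase subunit Prkaa2 (−1.98 ± 0.14) and Il17rd (−1.88 ± 0.15). Gbp2, also an interferon-induced GTPase, and the phosphatase Dusp15 followed at −1.87 ± 0.15 and −1.85 ± 0.37. The call of Dusp15 ended without any 1 of the 4 arrays, at −1.95 to −1.76.

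Among 32 macrophage markers, 11 rose and 2 fell with Ebf1 shRNA, against 13 and 2 adjusted over the list alone, with adjusted p = 0.0517 with an estimated correlation. The C-type lectin gene Clec4n (3.13 ± 0.13), the scavenger receptor Msr1 (2.77 ± 0.12), the galectin Lgals3 (2.37 ± 0.24) and the integrin Itgax (1.68 ± 0.12) changed most. Of 20 macrophage regulators, 3 rose and 1 fell, the same counts as adjusted over the list alone (adjusted p = 0.462 with an estimated correlation). Id2 rose by 1.80 ± 0.10, Tfec by 1.18 ± 0.10 and Cebpb by 0.70 ± 0.10, and Irf8, a factor of monocyte development, changed by −0.78 ± 0.10. Of 28 B lineage genes, 4 rose and 6 fell, against 6 and 7 adjusted over the list alone. Their median was −0.02 and their mean 0.05, camera gave the direction up with adjusted p = 0.623, and the median turned to 0.06 when arrays were centred. Il7r, the receptor for a growth factor of early lymphocytes, rose by 2.08 ± 0.10, Fcrla by 1.80 ± 0.15 and Sox4 by 1.53 ± 0.19. Lef1 changed by −1.35 ± 0.14 and the surrogate light chain gene Vpreb1 by −0.99 ± 0.21. Pax5, the B cell identity factor, stood at −0.82 ± 0.26 (adjusted p = 0.0864). The call of Vpreb1 ended without Ebf1 replicate 1 (−0.70) or scramble replicate 1 (−0.81) or 2 (−1.17). In limma, 775 genes rose and 1019 fell of 12484 tested, and centring each array turned this split to 941 and 660. Leaving out 1 array lowered the 1794 called genes to 821 without Ebf1 replicate 1, 825 without Ebf1 replicate 2, 507 without scramble replicate 1 and 624 without scramble replicate 2, with the lone array assumed to vary like the other groups.

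In the arrays labelled Pou2af1 shRNA, interferon response genes were higher than with scramble shRNA (n = 2 each). Of 21 such genes, 16 rose over all genes tested and 18 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 0.0286). Ifit3 rose by 2.31 ± 0.13, the antiviral GTPase Mx1 by 2.06 ± 0.10, Ifit2 by 1.82 ± 0.12 and the interferon regulator Irf7 by 1.38 ± 0.10, whereas Ddx58 stood at 0.39 and Oasl2 at 0.27. The membrane proteins Ms4a6b and Ms4a6c showed the highest increases, 4.85 ± 0.20 and 4.21 ± 0.15 (adjusted p = 0.000366 for both). The monocyte chemoattractants Ccl7 and Ccl12 rose by 3.53 ± 0.10 and 2.95 ± 0.30, Clec4n by 3.35 ± 0.13 and the interferon-inducible GTPase Iigp1 by 3.19 ± 0.22. The RNA-binding protein gene Strbp (−2.15 ± 0.14), the erythroid repressor Gfi1b (−2.01 ± 0.10) and the neutrophil chemoattractant Cxcl2 (−1.97 ± 0.09) changed most in the other direction. Ovgp1, Mageh1 and Prkaa2 followed at −1.86 ± 0.20, −1.85 ± 0.16 and −1.79 ± 0.14. Of 32 macrophage markers 12 rose and 0 fell, as many as adjusted over the list alone (adjusted p = 0.0675 with an estimated correlation). They included Msr1 (2.55 ± 0.12), the macrophage surface protein Adgre1 (2.46 ± 0.24) and the chemokine receptor Ccr2 (2.19 ± 0.15). Of 20 macrophage regulators 6 rose, or 7 adjusted over the list alone, and 0 fell, led by Maf (1.46 ± 0.20), Bhlhe41 (1.43 ± 0.18), Id2 (1.42 ± 0.10) and Tfec (1.06 ± 0.10), with adjusted p = 0.126 with an estimated correlation. Of 28 B lineage genes 12 rose and 2 fell, against 14 and 2 adjusted over the list alone (adjusted p = 0.102 with an estimated correlation). Il7r rose by 2.42 ± 0.10, the surrogate light chain genes Igll1 and Vpreb1 by 1.42 ± 0.16 and 0.99 ± 0.21, and the heavy chain gene Ighm by 1.04 ± 0.16. Pax5 stood at 0.99 ± 0.26 (adjusted p = 0.0576). Of 23 cytokine genes 8 rose and 3 fell, as adjusted over the list alone, among them Ccl4 (1.78 ± 0.13) and Tnfaip3, an inhibitor of NF-kappaB (1.49 ± 0.15), with adjusted p = 0.194 with an estimated correlation. The call of Vpreb1 ended without any 1 of the 4 arrays, at 0.80 to 1.17, and those of Maf (1.57 and 1.35) and Ighm (1.06 and 1.02) without scramble replicate 1 or 2. In limma, 848 genes rose and 642 fell. The 1490 called genes dropped to 355 without replicate 1 and 450 without replicate 2 of the Pou2af1 group, and to 399 and 406 without scramble replicates 1 and 2.

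Compared directly, the Ebf1 shRNA arrays lay below the Pou2af1 shRNA arrays in 21 of 21 interferon response genes, also when adjusted over the list alone, with a median difference of −1.55 (camera adjusted p = 0.0176). Ifit1bl1, Iigp1 and Ifit3 differed by −3.85 ± 0.10, −3.84 ± 0.22 and −3.76 ± 0.13, Ifit2 by −3.06 ± 0.12, Mx1 by −2.95 ± 0.10 and Ifit1 by −2.44 ± 0.11. The interferon-inducible genes Gbp3, Ifi213 and Gbp6 lay at −3.22 ± 0.12, −3.21 ± 0.16 and −3.20 ± 0.26. Stfa3 (5.83 ± 0.17), Cxcl2 (4.64 ± 0.09, adjusted p = 2.92e-05) and Wfdc21 (4.02 ± 0.11) were the highest, before Slc7a11 (3.97 ± 0.24), Mansc1 (3.71 ± 0.25) and Il1f9 (3.57 ± 0.12). Of 28 B lineage genes 5 were higher and 9 lower, against 7 and 13 adjusted over the list alone (adjusted p = 0.332 with an estimated correlation). The latter included Igll1 (−2.16 ± 0.16), Vpreb1 (−1.98 ± 0.21), Pax5 (−1.81 ± 0.26) and Ighm (−1.32 ± 0.16). Of 32 macrophage markers 7 were higher and 9 lower, against 8 and 11 adjusted over the list alone (adjusted p = 0.608 with an estimated correlation), with Lgals3 at 2.16 ± 0.24 and Itgam at 1.53 ± 0.11 but Adgre1 at −2.16 ± 0.24 and Fcgr1 at −2.07 ± 0.14. In limma, 886 genes were higher and 1162 lower, a split that centring turned to 1285 and 900. Without Ebf1 replicates 1 and 2 the 2048 called genes were 1246 and 1308, and without Pou2af1 replicates 1 and 2 they were 892 and 931.

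Against the shared scramble arrays, 243 genes rose with both shRNAs and 227 fell with both, where independent lists would share 52.6 and 52.4. Another 46 genes rose with Ebf1 and fell with Pou2af1 shRNA, and 96 did the opposite. Both comparisons used 1 spread estimate per gene, so genes with a small spread were called more easily in both, in either direction. Independent lists are therefore no fair reference, and the excess over them does not measure a shared response. Across the 12484 genes, which are not independent replicates, the log2 fold changes correlated with r = 0.34, and 100 simulations of unchanged groups against the same controls gave 0.50. That value follows from the shared controls by construction, and a response of either group also changes r. An r under 0.50 therefore does not show that the responses were less alike than unchanged groups. The covariance of the log2 fold changes was 0.0632 against 0.0169 in the simulations. The 2 scramble arrays were also divided between the shRNAs, an alternative chosen after seeing the data, so that no shared control built in a correlation. With replicate 1 for Ebf1 and 2 for Pou2af1 shRNA r was 0.22, with a covariance of 0.0443. The other way round r was 0.26, with a covariance of 0.0510.

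**Figure D2:**
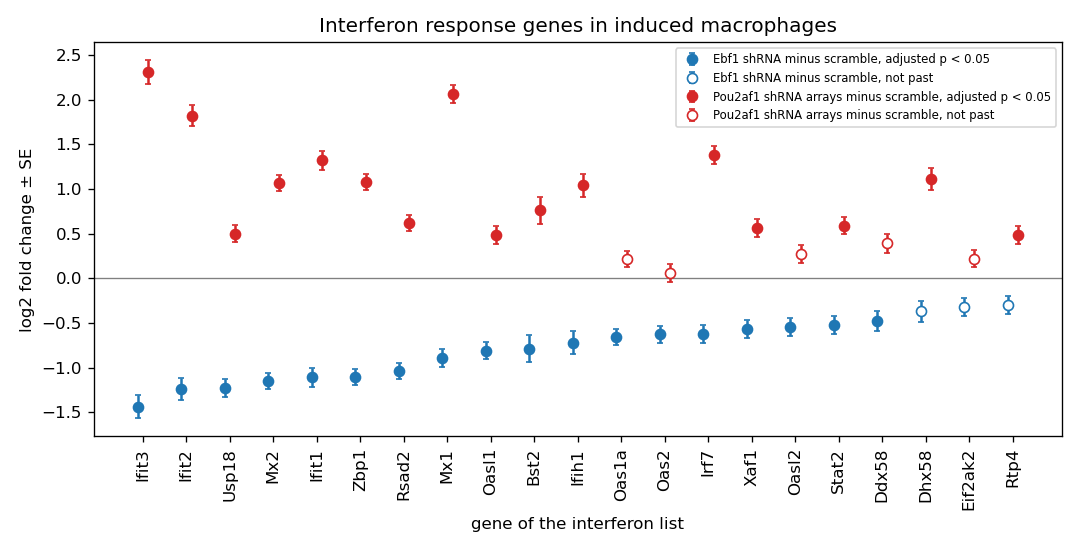
Log2 fold change ± SE of the 21 interferon response genes in Ebf1 shRNA and Pou2af1 shRNA arrays against the same scramble arrays (n = 2 arrays per group), with open points not past the threshold. The median over the list was −0.72 for Ebf1 and 0.62 for Pou2af1 shRNA arrays.

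Measured against adult liver, iHeps (n = 3 against 2) held far less RNA of hepatocyte metabolism, plasma protein and liver regulator genes. All 31 hepatocyte metabolism genes were lower, also when adjusted over the list alone, with a median of −7.23 (camera adjusted p = 0.0467). The glucuronosyltransferase Ugt2b1 (−9.86 ± 0.62), the cytochromes P450 Cyp2c29 (−9.48 ± 0.41) and Cyp1a2 (−9.27 ± 0.28) and the urea cycle enzyme Cps1 (−9.21 ± 1.05) differed most. Of 26 plasma protein genes 24 were lower, as adjusted over the list alone, with a median of −7.72 (camera adjusted p = 0.0467). The fibrinogen chain Fga (−10.08 ± 0.26), Itih3 (−9.91 ± 0.29), Serpina6 (−9.60 ± 0.68) and antithrombin, Serpinc1 (−9.46 ± 0.38), were among them. The iHep lines were not alike: the list mean was 7.02, 7.54 and 8.09 in replicates 1, 2 and 3. Albumin, Alb, was at 5.69, 9.90 and 11.59 in the same order, against 14.99 and 14.75 in adult liver. Apoa1, the main protein of high-density lipoprotein, was at 14.92 in iHep and 14.68 in liver (0.24 ± 0.28), and Fgb differed by −0.98 ± 0.66, neither past the threshold. Both Apoa1 levels lay near the highest value of any array (15.11), where saturation can hide a difference. Of 22 liver regulators 18 were lower and 1 higher, against 19 and 1 adjusted over the list alone, with a median of −3.09 (camera adjusted p = 0.0467). Onecut2 and the bile acid receptor Nr1h4 each lay at −6.07, with errors of 0.29 and 0.22, the fatty acid sensor Ppara at −5.52 ± 0.37 and Foxa2 at −5.26 ± 0.25. Gata6 stood at 1.03 and Gata4 at −0.89, not past it. Foxa1 and Hnf4a were lower by −3.32 ± 0.55 and −2.29 ± 0.77 (adjusted p = 0.000554 and 0.0289). Hnf4a lay at −1.30 without iHep replicate 1 and was no longer called without adult liver replicate 1 (−2.48) or 2 (−2.11).

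The genes highest in iHep over adult liver were the tetraspanin Tspan8 (9.05 ± 0.44, 12.94 ± 0.54 SD in iHep, adjusted p = 2.87e-07) and the peptide-processing enzyme Cpe (8.66 ± 0.46). Fgf13 (8.10 ± 0.58), the mucin-type glycosyltransferase Gcnt3 (7.90 ± 0.40), the retinoic acid-binding protein Crabp1 (7.89 ± 0.23) and Smgc (7.75 ± 1.09) came next. The lowest were the cytochrome Cyp3a25 (−10.75 ± 0.51), Ugt2b5 (−10.68 ± 0.60), the retinol dehydrogenase Rdh7 (−10.36 ± 0.19), the clotting factor subunit F13b (−10.22 ± 0.26), Elovl2 (−10.16 ± 0.40) and Mug1 (−10.16 ± 0.35). In each of these highest and lowest genes the lower group lay at 3.01 to 4.43, under the 40th percentile of its arrays, so the size and order of the differences also reflected each probe set's background. Of 24 intestinal regulators 8 were higher and 2 lower, as adjusted over the list alone, with adjusted p = 0.828 with an estimated correlation. Hoxa9 (6.67 ± 0.25), Klf4 (6.00 ± 0.44), Klf5 (5.52 ± 0.32) and Cdx2 (3.61 ± 0.39) were higher, with the last at adjusted p = 3.3e-05. Of 35 colon epithelium genes 13 were higher and 4 lower, against 12 and 3 adjusted over the list alone (adjusted p = 0.929 with an estimated correlation), and the list's median moved from 0.03 to −0.62 when arrays were centred. The goblet cell genes Clca1 and Tff3 stood at 7.47 ± 0.59 and 5.88 ± 0.68, and the water channel Aqp8 at −6.24 ± 0.51. Of 29 cell cycle genes 28 were higher, also adjusted over the list alone, with Birc5 at 6.73 ± 0.35, Rrm2 at 6.23 ± 0.33, Mcm6 at 6.11 ± 0.35 and Bub1 at 5.87 ± 0.34, though with adjusted p = 0.283 with an estimated correlation. Markers of other liver cells were lower than in the arrays labelled adult liver, whose cell content the labels leave open, with 11 of 11 Kupffer cell genes (Slc40a1 at −6.96 ± 0.39, Vsig4 at −6.91 ± 0.65) and 17 of 19 leukocyte genes (Ctss at −7.55 ± 0.54, Ptprc at −6.75 ± 0.78), as adjusted over each list alone, both with adjusted p = 0.186 with an estimated correlation. Of 10 gastric genes 3 were higher and 1 lower, as adjusted over the list alone, with the stomach peptide genes Gkn2 and Tff1 at 6.08 ± 0.90 and 3.79 ± 1.03. Their median was 0.25, camera gave the direction down (adjusted p = 0.929 with an estimated correlation), and centring turned the median to −0.40. The call of Tff1 ended without adult liver replicate 1, at 3.69. In limma, 5763 of 15262 genes were higher and 2774 lower. The median of all genes was 0.26 as deposited, −0.02 after repeated quantile normalization and −0.39 after centring, which gave splits of 4481 and 4096 and of 4016 and 5862.

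Against fetal liver, iHeps (n = 3 against 2) held far less RNA of erythroid genes. All 15 erythroid genes were lower, also adjusted over the list alone, with a median of −7.23 (camera adjusted p = 0.00322). The red cell membrane proteins Rhag (−9.65 ± 0.22, adjusted p = 1.98e-08) and Slc4a1 (−9.55 ± 0.48), the erythroid factor Nfe2 (−8.09 ± 0.26) and Trim10 (−7.99 ± 0.25) led them, beside Hemgn (−10.07 ± 0.42) and the haemoglobin gene Hbb-b2 (−9.45 ± 0.30). Olfm4 and the neutrophil protein gene S100a9 lay at −9.40 ± 0.22 and −9.26 ± 1.04. Of 19 leukocyte genes 16 were lower, or 17 adjusted over the list alone, with Ctss at −7.61 ± 0.54 and Lyz2 at −7.31 ± 1.21 (adjusted p = 0.179 with an estimated correlation). Of 26 plasma protein genes 18 were lower and 4 higher, as adjusted over the list alone, with Fga at −7.40 ± 0.26 and Itih3 at −6.50 ± 0.29 (adjusted p = 0.179 with an estimated correlation). Afp, the fetal counterpart of albumin, lay at −5.92 ± 0.91. The highest genes were Gcnt3 (8.98 ± 0.40), Smgc (8.72 ± 1.09), Cpe (8.71 ± 0.46), the matrix protein gene Mgp (7.83 ± 0.29), the glucose oxidation switch Pdk4 (7.77 ± 0.75) and Clca1 (7.65 ± 0.59). Of 24 epithelial genes 12 were higher and 1 lower, against 16 and 2 adjusted over the list alone (adjusted p = 0.233 with an estimated correlation). The keratins Krt19, Krt7 and Krt8 stood at 6.82 ± 0.42, 4.91 ± 0.89 and 4.53 ± 0.58, and the junction protein Tjp1 at 4.45 ± 0.32. Of 24 intestinal regulators 7 were higher and 0 lower, as adjusted over the list alone (Mycn 4.49 ± 0.40, Cdx2 4.17 ± 0.39, Hoxa9 3.23 ± 0.25, Klf5 3.01 ± 0.32), with adjusted p = 0.601 with an estimated correlation and a median of 0.12 that centring turned to −0.18. Of 22 liver regulators 2 were higher and 3 lower, as adjusted over the list alone, with a median of 0.09, which other scalings turned to −0.10 and −0.21, and a mean of −0.02 (adjusted p = 0.819 with an estimated correlation, direction down). Gata6 (2.01 ± 0.48) and Esrra (1.66 ± 0.24) were higher, Foxa3 (−1.70 ± 0.46) and Creb3l3 (−1.30 ± 0.36) lower, and Foxa1 stood at −1.11 ± 0.55. The call of Gata6 ended without fetal liver replicate 2 (1.61), and those of Foxa3 and Creb3l3 without iHep replicate 2 (−1.59 and −1.12) or fetal liver replicate 1 (−1.20 and −0.90). In limma, 3041 genes were higher and 1997 lower, a split that became 2502 and 2503 after repeated quantile normalization and 2207 and 3185 after centring, which moved the median of all genes from 0.05 to −0.25. Without fetal liver replicate 2 the 5038 called genes were 3007.

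Fetal liver held less RNA of hepatocyte genes and more of erythroid genes than adult liver (n = 2 each). Of 31 hepatocyte metabolism genes 30 were lower in fetal liver, also adjusted over the list alone, with a median of −5.96 (camera adjusted p = 0.0321). Cyp1a2 (−8.80 ± 0.31), Ugt2b1 (−8.63 ± 0.68), the glucose-releasing enzyme G6pc (−8.48 ± 0.36) and Cyp2f2 (−8.13 ± 0.38) were among them, and Hsd17b13 stood at −0.40 ± 0.22. Of 22 liver regulators 20 were lower, as adjusted over the list alone, with Onecut2 at −6.56 ± 0.32, Nr1h4 at −5.74 ± 0.24, Onecut1 at −4.67 ± 0.33 and Ppara at −4.59 ± 0.40 (median −2.57, camera adjusted p = 0.0389). Gata6, at −0.97, and Cebpb, at −0.25, were not past the threshold. All 15 erythroid genes were higher, also adjusted over the list alone (median 5.67, camera adjusted p = 0.0221), with Nfe2 at 7.35 ± 0.29 and the blood group antigen gene Kel at 7.25 ± 0.29. Of 26 plasma protein genes 24 were lower, as adjusted over the list alone, with Apoc3 at −8.03 ± 0.51 and Fetub at −7.41 ± 0.41 but Ttr at −1.08 and Alb at −0.64, not past it (adjusted p = 0.055 with an estimated correlation). All 29 cell cycle genes were higher, also adjusted over the list alone, with Birc5 at 7.83 ± 0.38 and Mcm6 at 7.29 ± 0.38 (adjusted p = 0.264 with an estimated correlation). Of 13 fetal liver and hepatoblast genes 6 were higher and 1 lower, against 7 and 1 adjusted over the list alone, with Afp at 7.58 ± 1.00, Igf2bp3 at 5.04 ± 0.30 (−0.40, not past the threshold, on another probe set, taken when those shared between transcripts were left out), Hmga2 at 3.90 ± 0.43 and Gpc3 at 3.67 ± 0.97 (adjusted p = 0.68 with an estimated correlation). The call of Gpc3 ended without fetal liver replicate 1 (3.09) or adult liver replicate 1 (3.46). Hemgn (9.51 ± 0.46), Rhag (9.19 ± 0.24, adjusted p = 4.67e-08), Olfm4 (9.17 ± 0.24), Slc4a1 (8.70 ± 0.52), Stfa3 (8.49 ± 0.28) and Bex1 (8.36 ± 0.70) were the highest. Cyp3a25 (−9.39 ± 0.56), Ugt2a3 (−9.17 ± 0.36), Ces1f (−9.13 ± 0.43), Cyp2c37 (−9.11 ± 0.36) and Mug1 (−9.07 ± 0.38) were the lowest beside Cyp1a2. In limma, 4748 genes were higher and 2777 lower. Repeated quantile normalization gave 4126 and 3748 and centring 3862 and 3928, with the median of all genes moving from 0.16 to −0.02 and −0.19.

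**Figure D3:**
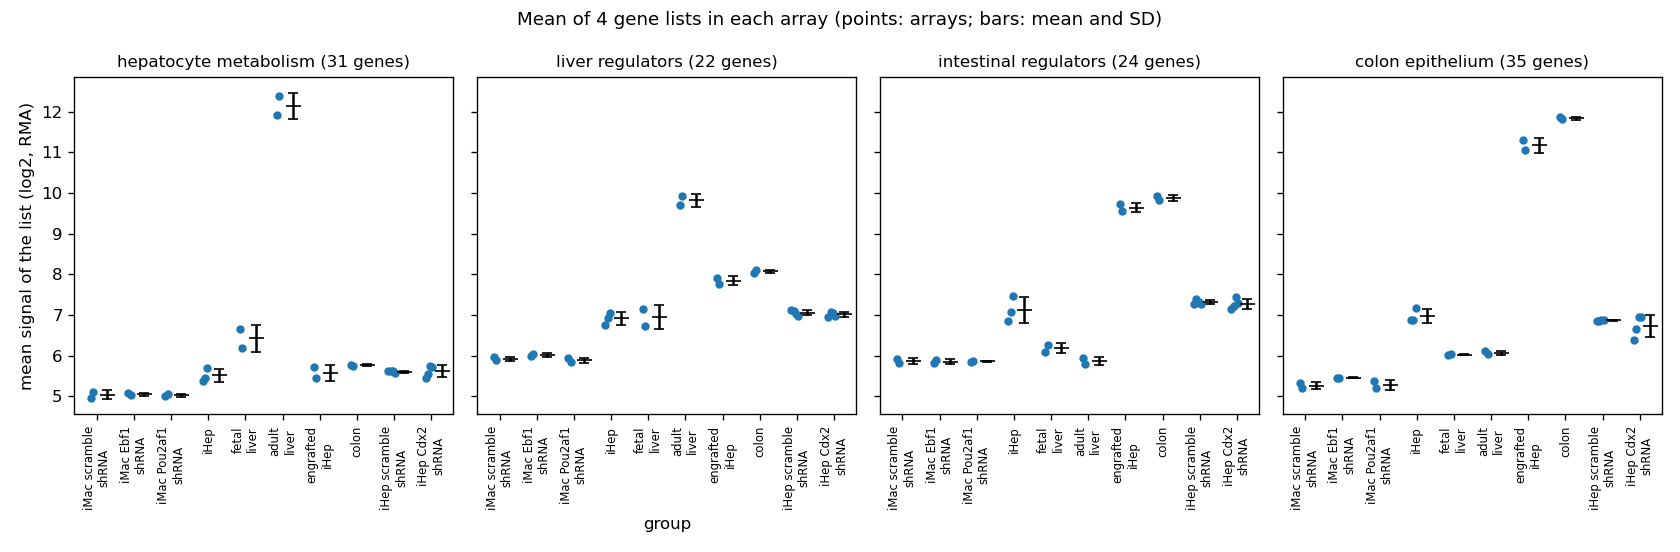
Mean log2 signal of 4 gene lists in each of the 25 arrays by group, with group means and SD. The hepatocyte metabolism list averaged 5.51 in iHep and 12.15 in adult liver, and the colon epithelium list 6.98 in iHep, 11.18 in engrafted iHep and 11.84 in colon.

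Compared with colon crypts, iHeps (n = 3 against 2) held far less RNA of colon epithelium and enteroendocrine genes. Of 35 colon epithelium genes 29 were lower, as adjusted over the list alone, with a median of −5.74 (camera adjusted p = 0.0229). Mptx1 (−8.93 ± 1.10), the mucin-folding protein gene Agr2 (−8.74 ± 0.34), the carbonic anhydrase Car1 (−8.37 ± 0.36) and Dmbt1 (−8.12 ± 0.41) were among them, whereas Tff3 stood at 1.19 ± 0.68 and Clca1 at −1.16 ± 0.59. Of 11 enteroendocrine genes 8 were lower, as adjusted over the list alone, with a median of −3.79 (camera adjusted p = 0.0406). The granule protein gene Chgb and the gut hormone genes Insl5, Pyy and Gcg lay at −7.20 ± 0.26, −6.10 ± 0.24, −5.95 ± 0.54 and −5.39 ± 0.27. Of 24 intestinal regulators 18 were lower and 2 higher, as adjusted over the list alone, with Ehf at −8.15 ± 0.19, Cdx1 at −6.48 ± 0.23, Creb3l1 at −5.48 ± 0.29, Cdx2 at −2.17 ± 0.39 and Mycn at 6.36 ± 0.40 (adjusted p = 0.0628 with an estimated correlation). Of 26 plasma protein genes 11 were higher and 2 lower, against 11 and 1 adjusted over the list alone, with Apoa1 at 8.41 ± 0.28, Fgb at 7.72 ± 0.66, Kng1 at 6.59 ± 0.26 and Hpx at 5.79 ± 0.94 (adjusted p = 0.593 with an estimated correlation). Of 22 liver regulators 3 were higher and 10 lower, as adjusted over the list alone, and Foxa1 (−5.91 ± 0.55), Foxa3 (−5.06 ± 0.46), Nr1h4 (−5.02 ± 0.22) and Hnf4a (−3.05 ± 0.77) were lower than in colon (adjusted p = 0.44 with an estimated correlation). Of 30 mesenchymal genes 14 were higher and 2 lower, as adjusted over the list alone, with Cdh2 at 7.89 ± 0.45, Fn1 at 6.91 ± 0.55 and Vim at 5.85 ± 0.49 (adjusted p = 0.593 with an estimated correlation). The highest genes after 1 probe set of Pik3cd (9.07 ± 0.27) were Mgp (8.87 ± 0.29), the protease inhibitor Serpina1b (8.87 ± 0.58), Apoa1, Gkn2 (8.38 ± 0.90) and Klhl13 (8.19 ± 0.57). The lowest were Sval1 (−9.54 ± 0.29), Slfn4 (−9.50 ± 0.71), Gsdmc2 (−9.27 ± 0.57), Lypd8 (−8.98 ± 0.37), Mptx1 and Tmem45b (−8.93 ± 0.31). In limma, 4926 genes were higher and 3247 lower, and the median of all genes was 0.22, 0.08 after repeated quantile normalization and 0.11 after centring. All 15 iHep and liver arrays carried signal from the poly-A spike controls (8.13 to 10.18) and the 10 macrophage, engrafted and colon arrays did not (3.71 to 4.08). The colon against iHep difference therefore crossed this divide, and the divide and the groups could not be told apart. Genes whose values separated all arrays of one kind from all of the other made up 1561 of the 15262 genes tested and 1419 of the 8173 called. The compared arrays helped to define these separating genes, so most were called by construction. Among them were Serpina1b, Apoa1, Fgb, Kng1, Hpx, Cdh2, Ehf, Creb3l1 and Pik3cd, the last at 12.78 to 14.21 in every array with spike signal and 3.46 to 4.54 in every other array. Of the other 5 Pik3cd probe sets 4 overlapped between the kinds of array, and the last read 2.94 to 5.51 against 2.41 to 2.73.

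The cells sorted as engrafted iHeps (n = 2 against 3) held more RNA of colon epithelium, intestinal regulator, enteroendocrine and duct genes than cultured iHeps. Here and in the next paragraph a rise is a difference between these arrays. Host colon cells, a mix with them and a change of the iHeps could not be told apart. Eif2s3y, given in the next paragraph, argued against cells of the 3 profiled iHep lines alone. A change of another iHep line stayed open. Of 35 colon epithelium genes 29 were higher, or 30 adjusted over the list alone, with a median of 4.66 (camera adjusted p = 0.0184). Agr2 rose by 9.18 ± 0.34 to 12.96 ± 0.21 (SD, adjusted p = 1.26e-07), the chloride channel Cftr by 8.12 ± 0.21, Dmbt1 by 7.76 ± 0.41 and the carbonic anhydrase Car4 by 7.67 ± 0.19, whereas Clca1 stood at 1.45 ± 0.59 and Retnlb at 0.77. Of 24 intestinal regulators 19 were higher and 0 lower, against 19 and 1 adjusted over the list alone, with a median of 2.41 (camera adjusted p = 0.0324). The transcription factor genes Ehf, Creb3l1, Cdx1 and Hnf4g rose by 7.60 ± 0.19, 5.33 ± 0.29, 5.22 ± 0.23 and 4.59 ± 0.31, and Cdx2 by 1.58 ± 0.39, whereas Mycn stood at −0.99 ± 0.40 and Foxd2 at −0.97. Of 11 enteroendocrine genes 8 were higher, or 9 adjusted over the list alone (median 2.91), and of 13 cholangiocyte and oval cell genes 10 were higher and 2 lower, as adjusted over the list alone (median 2.22), both with camera adjusted p = 0.0324. Chgb rose by 8.58 ± 0.26, Chga by 3.62 ± 0.95, the neuropeptide gene Tac1 by 3.36 ± 1.10 and the serotonin enzyme Tph1 by 3.07 ± 0.51, but Insl5 stood at 0.25 ± 0.24. Without engrafted replicates 1 and 2, Chga lay at 1.41 and 5.84 and Tac1 at 1.09 and 5.62, Tph1 lay at 1.96 without replicate 1, and the call of Tac1 ended without engrafted replicate 1 or without iHep replicate 1 (2.87) or 2 (3.13). Prom1, a surface protein of stem cells and ducts, rose by 7.98 ± 0.22, the water channel Aqp1 by 4.22 ± 0.36 and the anion exchanger Slc4a2 by 3.81 ± 0.26. Of 19 intestinal stem cell genes 10 were higher and 3 lower, as adjusted over the list alone, with Olfm4 at 6.94 ± 0.22, Rnf43 at 5.11 ± 0.51 and Axin2 at 2.50 ± 0.30 (adjusted p = 0.0586 with an estimated correlation). The highest genes outside these lists were the brush border enzyme Mgam (8.59 ± 0.35), Lypd8 (8.54 ± 0.37), Sval1 (8.54 ± 0.29) and Tmem45b (8.41 ± 0.31). Cultured iHeps lay at 3.51 to 4.81 in Agr2, Chgb, Mgam, Lypd8, Sval1 and Tmem45b, under the 40th percentile of their arrays, so background limited the size of these increases. Car4, Ehf, Creb3l1 and Slc4a2 were among the genes that separated all arrays with spike signal from all arrays without it.

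Among liver genes, 9 of 26 plasma protein genes were lower and 4 higher in engrafted than in cultured iHeps, against 11 and 4 adjusted over the list alone, with a median of −0.78 (adjusted p = 0.868 with an estimated correlation). Fgb (−7.44 ± 0.66), Kng1 (−6.27 ± 0.26), Hpx (−5.98 ± 0.94) and Apoa1 (−4.88 ± 0.28) were lower, whereas Ttr stood at 3.69 and Alb at −2.81 ± 1.29, not past the threshold. Of 22 liver regulators 8 were higher and 2 lower, as adjusted over the list alone (adjusted p = 0.431 with an estimated correlation). Foxa3 rose by 5.39 ± 0.46, Foxa1 by 4.50 ± 0.55, Nr1h4 by 3.95 ± 0.22 and Hnf4a by 2.49 ± 0.77, which was 1.5 without iHep replicate 1 and no longer called without engrafted replicate 1 (2.45) or 2 (2.53). Of 13 fetal liver genes 7 were lower and 2 higher, as adjusted over the list alone, with the growth factor Igf2 at −5.72 ± 1.41 and Dlk1 at −3.60 ± 0.95 (adjusted p = 0.92 with an estimated correlation). With probe sets shared between transcripts left out, another probe set gave Dlk1 0.39, not past the threshold. The probe set taken for Pik3cd (−9.07 ± 0.27), 1 of 6, Bex4 (−8.23 ± 0.40), Crabp1 (−7.96 ± 0.23), Fgf13 (−7.66 ± 0.58), Fgb and Smgc (−7.11 ± 1.09) were the lowest. Of 30 mesenchymal genes 6 were lower and 3 higher, against 6 and 2 adjusted over the list alone, with Cdh2 at −4.93 ± 0.45 and the collagen genes Col3a1 and Col1a1 at 4.03 ± 1.13 and 3.39 ± 1.17 (adjusted p = 0.956 with an estimated correlation). Col1a1 was at 7.82 in engrafted replicate 1 and 12.82 in replicate 2, and the macrophage lysozyme gene Lyz2 at 6.11 and 11.37. Without engrafted replicate 2 the calls of Dlk1 (−3.09), Col3a1 (2.13) and Col1a1 (0.89) ended, the last also without iHep replicate 1 (2.70) or 2 (3.62), and Col1a1 lay at 5.89 without engrafted replicate 1. Of 19 leukocyte genes 4 were higher and 2 lower, as adjusted over the list alone, with Ctss at 6.18 ± 0.54 (adjusted p = 0.868 with an estimated correlation). The Y-linked genes Eif2s3y and Kdm5d, chosen after their values were seen, were at 9.27 to 9.33 and 9.14 to 9.67 in engrafted iHep against 3.48 to 3.81 and 3.94 to 5.03 in the iHep lines and 6.25 to 6.36 and 4.90 in colon. The Kdm5d probe set used was at 4.33 to 4.82 in fetal liver, where Eif2s3y was at 9.38 to 10.15, so its low iHep level was not informative. A second Kdm5d probe set was at 5.87 and 6.21 in engrafted iHep, 2.90 to 3.62 in iHep, 3.14 to 3.37 in colon and 6.68 to 6.77 in fetal liver. Uty, also Y-linked, was at 5.35 and 4.27 in engrafted replicates 1 and 2, the latter within the 3.86 to 4.33 of iHep, against 7.56 to 8.16 in macrophages. In limma, 2782 genes were higher and 4539 lower of 15262, with splits of 3193 and 3855 after repeated quantile normalization and 3392 and 3602 after centring, which moved the median of all genes from −0.22 to −0.08 and −0.02. Engrafted arrays lacked the spike signal that iHep arrays carried, and the divide and the groups could not be told apart. Genes that separated the arrays by spike signal made up 1561 of the 15262 genes tested and 1431 of the 7321 calls. Among them were Fgb, Kng1, Hpx, Apoa1, Dlk1, Pik3cd, Bex4 and Cdh2. The compared arrays helped to define these separating genes, so most were called by construction.

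**Figure D4:**
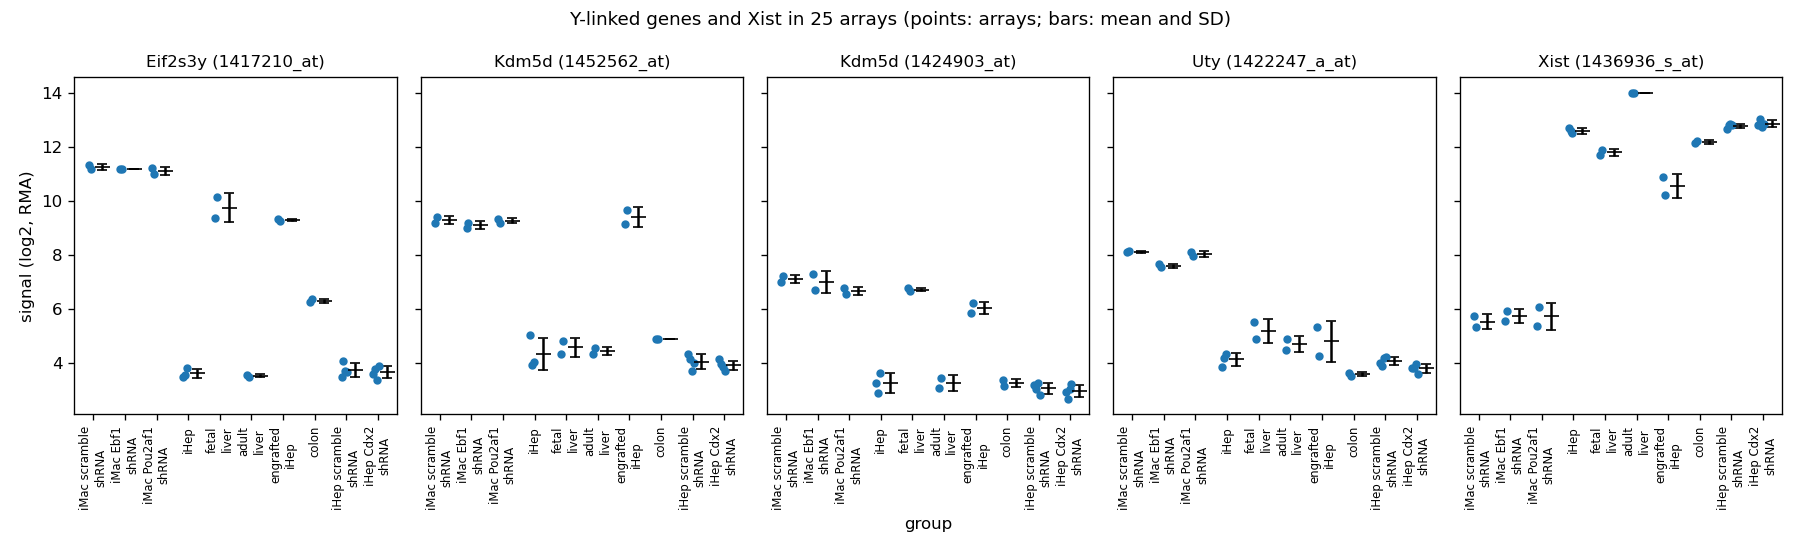
Signal (log2, RMA) of the Y-linked genes Eif2s3y, Kdm5d (both probe sets) and Uty and of the X inactivation RNA Xist in each of the 25 arrays by group, with group means and SD. Engrafted iHep arrays reached 9.27 to 9.33 for Eif2s3y, the iHep arrays 3.48 to 3.81 and the colon arrays 6.25 to 6.36, while Uty was at 5.35 and 4.27 in engrafted iHep.

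Set beside colon crypts, engrafted iHeps (n = 2 each) differed in 2557 of 15262 genes, and 0 lists passed the camera test. The engrafted cells came from the damaged colon of immunodeficient mice, and the crypts from undamaged colon. Damage, the host and the cells held could therefore not be told apart from engraftment. Of 21 interferon response genes 18 were lower, or 21 adjusted over the list alone, with a median of −3.67 (adjusted p = 0.316 with an estimated correlation). The mean of this list was 8.49 and 6.88 in engrafted replicates 1 and 2, against 11.51 and 11.41 in colon. Ifit1 lay at −6.49 ± 1.64, with 6.24 ± 4.13 (SD) in engrafted iHep, Ifit2 at −5.18 ± 0.78, Zbp1 at −4.71 ± 0.39 and Mx1 at −4.62 ± 0.45. Of 29 cell cycle genes 24 were higher, or 27 adjusted over the list alone, with Nusap1 at 3.01 ± 0.31, Cdc20 at 2.83 ± 0.38 and Cdc6 at 2.77 ± 0.51 (adjusted p = 0.316 with an estimated correlation). Of 19 intestinal stem cell genes 7 were higher, or 8 adjusted over the list alone, and 0 lower (adjusted p = 0.0965 with an estimated correlation). Olfm4 was higher by 6.69 ± 0.24, Cd44 by 3.36 ± 0.64, Smoc2 by 2.79 ± 0.76 and Bmi1 by 1.54 ± 0.30, whereas Lgr5, a marker of crypt base stem cells, stood at 2.16 ± 0.68, not past the threshold. The complement regulator Cfi (6.98 ± 0.29, adjusted p = 2.24e-06), the antimicrobial lectins Reg3g and Reg3b (6.74 ± 1.15 and 6.72 ± 0.85), Npnt (6.33 ± 0.39) and the protease gene Mmp7 (5.75 ± 0.23) were the highest beside Olfm4. Nxpe4 (−6.71 ± 0.61), Slfn5 (−6.61 ± 0.42), Trim30a (−6.05 ± 1.42), the hormone gene Insl5 (−5.85 ± 0.27) and the neutrophil protein gene S100a8 (−5.60 ± 0.82) were the lowest beside Ifit1. Of 35 colon epithelium genes 2 were higher and 9 lower, against 2 and 11 adjusted over the list alone, with Ang4 at 5.34 ± 0.31, Mptx1 at −4.76 ± 1.20, Slc9a3 at −3.21 ± 0.41 and Car1 at −2.71 ± 0.39 (adjusted p = 0.506 with an estimated correlation). Of 30 mesenchymal genes 7 were higher, as adjusted over the list alone, and 0 lower, with Fn1 at 5.66 ± 0.61, Vim at 3.31 ± 0.54, Cdh2 at 2.97 ± 0.49 and Zeb1 at 2.36 ± 0.54 (adjusted p = 0.597 with an estimated correlation). The mean of the mesenchymal list was 6.48 and 8.71 in engrafted replicates 1 and 2, against 5.62 and 5.66 in colon. Vim was at 10.65 and 11.58 in the engrafted arrays, between colon (7.62 to 7.99) and iHep (13.29 to 13.88). Of 11 enteroendocrine genes 3 were higher and 3 lower, against 5 and 3 adjusted over the list alone, with a median of 0.17 and a mean of −0.87 (adjusted p = 0.884 with an estimated correlation, direction down). Gcg and Pyy lay at −5.55 ± 0.30 and −3.40 ± 0.59 and the endocrine factor Pax4 at 1.49 ± 0.34. Of 24 intestinal regulators 3 were higher and 2 lower, against 3 and 3 adjusted over the list alone, with Mycn at 5.36 ± 0.44, the endocrine progenitor factor Neurog3 at 3.64 ± 0.25 and Cdx1 at −1.26 ± 0.25, and with Cdx2 at −0.59 ± 0.42, not past it (adjusted p = 0.879 with an estimated correlation). Without colon replicate 1 or 2, in this order, the calls of Ifit1 (−6.51 and −6.47), Trim30a (−6.10 and −6.01), Mptx1 (−4.72 and −4.81) and Cdx1 (−1.22 and −1.30) ended. So did those of Cd44 (3.29 and 3.42), Smoc2 (2.81 and 2.77), Bmi1 (1.45 and 1.63), Zeb1 (2.17 and 2.56) and Pax4 (1.24 and 1.73). The call of Cdc6 ended without colon replicate 1 (2.33). Without engrafted replicate 2 the calls of Ifit1 (−3.57), Trim30a (−4.31) and Smoc2 (2.21) ended, with Mptx1 at −7.36 and Zeb1 at 1.42, and without replicate 1 Mptx1 lay at −2.17, Pyy at −2.23 and Pax4 at 0.94. In limma, 1083 genes were higher and 1474 lower, a split that centring turned to 1310 and 1147. Without colon replicates 1 and 2 the 2557 called genes were 774 and 779, and without engrafted replicates 1 and 2 they were 3705 and 2597.

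In iHeps, Cdx2 and scramble shRNA arrays (n = 4 each) differed in 302 of 13650 genes, 73 higher and 229 lower with Cdx2 shRNA. Of the 35 splits of these arrays 2 reached this count, the real one among them. The calls, errors and adjusted p of this paragraph come from the planned model, which did not pair same-numbered arrays. With the replicate number as a block, 760 genes were called. The adhesion molecule gene Ceacam1, found on hepatocyte and gut epithelium, fell by 4.09 ± 0.35 to 7.42 ± 0.82 (SD) from 11.51 ± 0.23 (adjusted p = 0.00243). In the untransduced iHep arrays Ceacam1 was at 11.25, 8.02 and 9.50, so its level also varied widely without an shRNA. The secreted serpin gene Serpinf1 (−2.66 ± 0.43), the inflammasome sensor Naip5 (−2.57 ± 0.24) and the interferon-induced genes Ifi27l2a (−2.46 ± 0.51) and Ddx60 (−2.25 ± 0.28) also fell, as did the respiratory chain subunit Cox7a1 (−2.21 ± 0.35). The lubricating proteoglycan gene Prg4 rose by 2.64 ± 0.24, Afp by 2.38 ± 0.45 to 11.35 ± 0.94 (SD), the matrix protein gene Prelp by 1.75 ± 0.19 and the dipeptidase Dpep1 by 1.73 ± 0.30. Afp was at 5.95, 7.58 and 10.05 in the untransduced iHep arrays. Phex and the metalloprotease Adamts1 rose by 1.72 ± 0.24 and 1.60 ± 0.24. Of 21 interferon response genes 6 fell, and 20 adjusted over the list alone, with a median of −1.15. The list mean was 9.21 and 9.14 in Cdx2 shRNA replicates 1 and 2 but 8.04 and 8.01 in replicates 3 and 4, against 9.70 to 9.81 with scramble shRNA. In the untransduced iHep arrays it was 7.35, 9.43 and 9.07, also below the scramble arrays. A fall with Cdx2 shRNA and a raised scramble level could therefore not be told apart. The estimated correlation among the 21 interferon genes was 0.838, and no list was called (adjusted p = 0.819 with an estimated correlation for this list). Usp18 changed by −2.01 ± 0.38, Ifit1 by −1.70 ± 0.34, Zbp1 by −1.28 ± 0.20 and Mx1 by −0.68 ± 0.13, while Oasl2 stood at −1.99 and Ifit3 at −1.69 ± 0.36. Of 18 liver regulators 1 fell, as adjusted over the list alone, namely Hnf4a at −0.89 ± 0.18 (adjusted p = 0.044), and the list's median of −0.02 turned to 0.01 when arrays were centred. Hnf4a was also a transgene of these cells, and the arrays do not separate transgene from endogenous RNA. Its other probe sets read 7.95 to 8.96, 4.83 to 6.04 and 6.13 to 6.45 with scramble shRNA. With Cdx2 shRNA they read 7.05 to 7.84, 4.58 to 5.16 and 6.29 to 6.41, in the same order. Of 17 intestinal regulators 1 rose, the secretory cell factor Spdef (0.84 ± 0.12), as adjusted over the list alone, while Gfi1 stood at 1.00 and Hoxd10 at −0.92. Of 24 colon epithelium genes 0 were called over all genes and 3 were lower adjusted over the list alone, with Lgals4 at −1.04 ± 0.23 (adjusted p = 0.0543). The plasma protein gene Fetub rose by 0.99 ± 0.11 and the tyrosine catabolism enzyme Tat by 0.71 ± 0.14, each the only called member of its list of 20 and 11 genes. Adjusted over the list alone, 1 plasma protein gene rose, and 2 metabolism genes rose and 2 fell, with a metabolism median of 0.08 and mean of −0.10. Of 27 mesenchymal genes 3 rose and 1 fell, against 5 and 2 adjusted over the list alone, with the collagen crosslinking enzyme Lox at 1.39 ± 0.25, Fap at −1.05 ± 0.15, Sparc at 0.85 ± 0.16 and Col5a2 at 0.83 ± 0.16. For each of these lists the camera adjusted p was 0.819, and camera gave the direction up for metabolism genes.

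With the replicate number as a block, limma called 760 genes for Cdx2 shRNA, 242 higher and 518 lower, of which 289 were among the 302, and 10 of the 21 interferon genes were lower. With this block 4 of 24 colon epithelium genes were lower and 0 higher, 5 of 29 cell cycle genes were higher and 5 of 18 p53 and stress genes lower, and again no list was called. The block ended the calls of Hnf4a and Ifit1 and added that of Lgals4. Whichever array was left out, Cdx2, Ceacam1, Naip5, Ddx60, Prg4, Prelp, Phex, Fap and Fetub stayed past the threshold, whereas each other called gene named here lost its call without at least 1 array, though its log2 fold change stayed at 85% to 118% of the value given. Repeated quantile normalization gave 97 higher and 186 lower genes and centring 96 and 171. Without scramble replicates 1, 2, 3 and 4 the count of called genes was 130, 94, 123 and 56, without Cdx2 shRNA replicates 2 and 3 it was 92 and 168, and without replicates 1 and 4 it was 224 and 203.

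Along the axis from colon to adult liver, iHeps lay at 0.38 ± 0.02 (SD, n = 3), engrafted iHeps at 0.08 (n = 2) and fetal liver at 0.57 ± 0.01 (n = 2). On the 753 genes higher in liver, iHeps reached 0.15 ± 0.01 and fetal liver 0.30 ± 0.04, and on the 1113 genes higher in colon 0.54 ± 0.02 and 0.82 ± 0.01. Engrafted iHeps lay at 0.03 on the liver genes and 0.13 ± 0.02 on the colon genes. Engrafted and cultured iHeps differed by −0.30, with an exact permutation p of 0.1, the smallest that 10 assignments can give. The axis ends and these groups lay on opposite sides of the divide in spike signal, so position and array processing could not be told apart. Without the genes that separated arrays by spike signal, an alternative chosen after seeing the data, 1505 axis genes gave a difference of −0.17. The difference went from −0.41 to −0.34 on the colon genes and from −0.11 to −0.04 on the liver genes. The compared arrays and the axis ends helped to define the genes left out, so the smaller differences do not measure array processing. Induced macrophages, which are neither tissue, lay at 0.17 to 0.19, at 0.01 to 0.02 on the liver genes and at 0.55 to 0.59 on the colon genes. Without the separating genes, which were chosen partly on the macrophage arrays, macrophages lay at 0.28 to 0.32 and iHeps at 0.27, so their order turned. They lay at 0.83 to 0.86 and 0.49 on the colon genes, and at 0.01 to 0.02 and 0.08 on the liver genes. With Cdx2 shRNA iHeps lay at 0.40 ± 0.01 and with scramble shRNA at 0.38 ± 0.01 (n = 4 each), a difference of 0.02 with an exact permutation p of 0.0286, the smallest that 70 assignments can give. These assignments exchange arrays freely. Exchanging signs within the 4 same-numbered pairs, a test chosen after seeing the data, gave an exact permutation p of 0.125, the smallest that 16 assignments can give, so this test could not have passed the threshold and decides nothing. In 4 of the 4 pairs Cdx2 shRNA lay higher over all axis genes and over the colon genes, and in 2 over the liver genes. The difference came to 0.05 on the colon genes (exact permutation p = 0.0286, 0.125 within pairs and 0.114 without the separating genes) and to 0.01 on the liver genes (exact permutation p = 0.657). With a minimum difference of 2 for axis genes the exact permutation p was 0.0857, and with fetal liver as the liver end it was 0.257, in a range from 0.0286 to 0.914 over the alternatives.

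**Figure D5:**
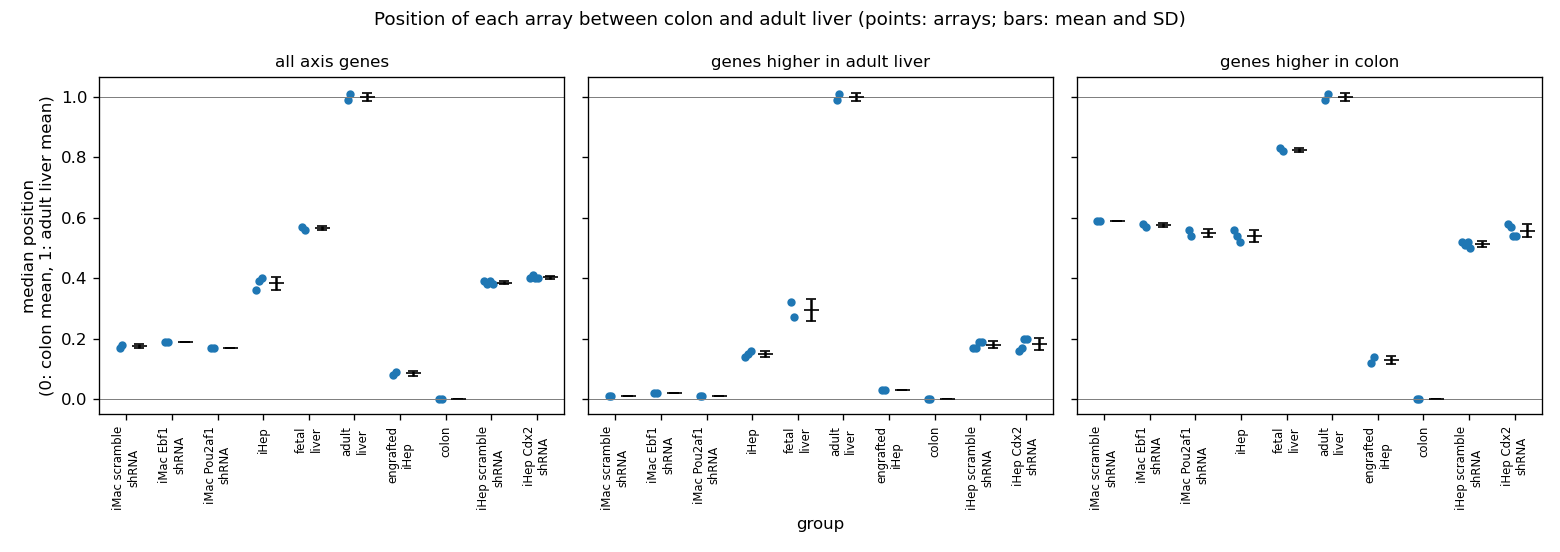
Median position of each of the 25 arrays between the colon mean (0) and the adult liver mean (1) over all axis genes, over the genes higher in liver and over the genes higher in colon, with group means and SD. Cultured iHeps lay at 0.38 and engrafted iHeps at 0.08.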

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

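The count over 35 splits of the Cdx2 shRNA arrays was planned. The limma comparisons and camera list tests given in this part were also planned, as was leaving each array out in turn. The replicate block was planned as an alternative and used as a test later. The other tests in this part, and the bounds they were read against, were chosen after the results were seen.

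Cdx2 was at 7.78 in Cdx2 shRNA iHep replicate 1 against 8.01 to 8.03 in the other 3 arrays, a gap wide for its group; 64 groups were looked at in this way, 1 stood out, and chance gives about 1 in 20. The Ebf1 and Pou2af1 shRNA arrays, called in opposite directions against the same scramble arrays, differed from each other in a direct limma test in Ifit3 (−3.76), Ifit2 (−3.06), Vpreb1 (−1.98) and Cxcl2 (4.64). The direct test does not show that each group moved from scramble, and for Vpreb1 both calls against scramble ended with the replicate block. The Pou2af1 call of Vpreb1 also ended without any 1 of the 4 arrays (0.80 to 1.17), and the Ebf1 call without Ebf1 replicate 1 (−0.70) or scramble replicate 1 (−0.81) or 2 (−1.17). The interferon list as a whole differed by a median of −1.55 (camera adjusted p = 0.0176). Poly-A spike control probe sets, used in no comparison, were higher by 4.49 in 15 arrays than in the other 10. In those 15 arrays the signal for 18S ribosomal RNA was 11.81 to 13.38, against 14.52 to 14.79 in the other 10.

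Colon epithelium genes lay higher in engrafted than in cultured iHeps by a median of 4.66. A uniform shift of these genes between arrays with and without spike signal was argued against by induced macrophages. These also lacked the signal, and their median over the same 35 genes differed from iHep by −0.52. Their list means were 5.26 to 5.45, against 6.98 in iHep, so they held little of this RNA. They could not show an effect of labelling or array processing on colon RNA that is present, which stays open. Host colon cells with no iHeps among them, which the sort for green fluorescence would remove, stayed open: over 627 genes raised in iHep above both livers, engrafted arrays exceeded colon by 0.08 in replicate 1 and 0.33 in replicate 2 relative to other genes, and 18% of them against 6.63% of other genes were called higher than in colon. The explanation was at the start taken as met from the lower array alone, and after the values were seen the reading was changed to need both arrays. A mix of iHeps and cells of the damaged host colon also stays open. In the engrafted arrays 242 of 15262 genes were at least 1 higher on the log2 scale than in iHep and in undamaged colon. A mix with undamaged colon would not give this, but damaged colon was not analysed here and the count decides nothing. These sources cannot be told apart from each other or from a change of the iHeps on engraftment, which was not tested. The Y-linked genes of the next paragraph argued against cells of the 3 profiled iHep lines alone, but not against another iHep line.

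The Y-linked genes Eif2s3y and Kdm5d were high in both engrafted arrays, a second Kdm5d probe set was at 5.87 and 6.21, and Uty was at 5.35 and 4.27 against 3.86 to 4.33 in iHep and 3.53 to 3.64 in colon. Cells of the 3 profiled iHep lines alone were argued against by Eif2s3y, which exceeded the highest iHep array by 5.46. The colon arrays, without spike signal, still read Eif2s3y at 6.25 to 6.36, with the second Kdm5d probe set at 3.14 to 3.37. Part of this excess over iHep may therefore not be Y-linked RNA. Labelling or array processing was argued against by Kdm5d, which exceeded the highest colon array, also without spike signal, by 4.23; that probe set was at 4.33 to 4.82 in fetal liver, where Eif2s3y was at 9.38 to 10.15, so its level in iHep was not used. Cells of male recipients could be a source, though the sort for green fluorescence would remove unlabelled ones: Eif2s3y exceeded the highest colon array by 2.90, but the recipients' sex, and that of any other iHep line, was not given in the sources used here, so these cannot be told apart. Xist was at 10.24 to 10.89 in the engrafted arrays, between the macrophages (5.34 to 6.09) and the iHep lines (12.52 to 12.73).

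For Cdx2 shRNA, 2 of the 35 splits of the 8 arrays into groups of 4, the real one among them, called at least the real 302 genes, so chance could not be excluded by this count. The other of these called 1053 and set replicates 1 and 2 of both groups against replicates 3 and 4, which points to a structure of the samples that runs across the groups. Among the 8 splits that part all 4 same-numbered pairs, the real one called 302 and the highest other 0, but 8 splits are too few for a share under 0.05. The replicate block called 760 genes, but each number occurred once in each group, so the block left the fold changes as they were and its count decides nothing about the spread between replicate numbers. A response to lower Cdx2, which the design names, stays open as a hypothesis.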

How the results depend on the processing

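Centring and leaving out genes that separate the arrays by spike signal were chosen after seeing the data, as were exchanging signs within pairs, leaving out these genes on the axis and dividing the scramble arrays; the other alternatives were planned. Of the 10 comparisons, counts stayed within 1.5 times of the main count except as given here, and the cause was not tested unless the alternative's own construction shows it. Without a filter, Ebf1 against scramble shRNA called 1120 genes and Pou2af1 923; a trend with robust fitting called 2856 and 2551. All 25 arrays in 1 model gave 432 for Ebf1, 315 for Pou2af1, 659 between these shRNAs, 5540 for engrafted iHep against colon and 73 for Cdx2 shRNA. A minimum change of 1 on the log2 scale, which drops smaller changes, left 410, 359, 574 and 76 for Ebf1, Pou2af1, their difference and Cdx2 shRNA. With untransduced iHeps added to the scramble group, Cdx2 shRNA called 42. Within 1.5 times, leaving out genes that separate arrays by spike signal gave 6625 for iHep against colon and 5711 for engrafted against cultured iHep. The compared arrays helped to define those genes, so the lower counts do not measure array processing. The replicate block gave 760 for Cdx2 shRNA, changed no list call there, and elsewhere kept counts within 1.5 times; numbers were not taken to pair the macrophage arrays (correlations of 0.05, 0.01 and 0.01), where it gave 1413, 1085 and 1838 genes. Leaving out 1 array gave 507 to 825 genes for Ebf1, 355 to 450 for Pou2af1, 892 to 1308 between them, 3007 to 4518 for iHep against fetal liver, 774 to 3705 for engrafted iHep against colon and 56 to 224 for Cdx2 shRNA. Of 170 list tests, 17 passed, 64 with a preset correlation, 87 with fry, which asks whether a list's genes move one way, and 20 without a filter, each holding all 17 with 0 opposite. The correlation of the macrophage responses was 0.318 with the mean of probe sets, and 0.217 and 0.258 with the scramble arrays divided between the shRNAs. The Cdx2 axis shift was 0.022 with a minimum of 2, 0.043 with fetal liver as its end and 0.006 on liver genes, none past the threshold, and 0.019 with signs exchanged within same-numbered pairs, where 16 assignments cannot pass it. Without genes that separate arrays by spike signal it was 0.020, past the threshold, but 0.046 on colon genes and 0.001 on liver genes, not past it, and the engrafted shift of −0.298 became −0.174. Among 377 named gene values, 3 reversed when shared probe sets were left out: Dlk1 in engrafted against cultured iHep (0.39) and Igf2bp3 in fetal against adult liver (−0.40) and in iHep against adult liver (−0.67), whose probe sets that alternative replaces. Of 5268 alternative values of named genes, 4966 kept their side of the threshold, 228 lost it and 71 gained it. Dim genes near background limit what arrays can show.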

Other observations

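The genes of the next paragraph and the interferon means per group were chosen after their values were seen, and no test beyond the comparisons above was run for this part.

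Several genes stood above both cultured iHeps and undamaged colon in the engrafted arrays (n = 2). Lgals2, a galectin, was at 13.30 ± 0.09 (SD) against means of 6.93 and 7.89, and the water channel Aqp5 at 10.91 ± 0.24 against 5.63 and 5.48. The antimicrobial genes Ang4 and Reg3b were at 10.72 ± 0.29 against 5.43 and 5.38 and at 11.80 ± 0.04 against 6.61 and 5.09. The stomach peptide gene Gkn3 was at 11.11 ± 0.41 against 6.69 and 5.55.

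The mean of the interferon list was 8.62 ± 1.11 (SD, n = 3) in iHep, 9.74 ± 0.05 (n = 4) with scramble shRNA, 8.60 ± 0.66 (n = 4) with Cdx2 shRNA, 7.69 ± 1.14 (n = 2) in engrafted iHep and 11.46 ± 0.07 (n = 2) in colon. The p53 and stress list held 11 of 18 genes higher in iHep than in adult liver, as adjusted over the list alone (adjusted p = 0.519 with an estimated correlation), with Ccng1 at 4.39 ± 0.21 (log2 fold and SE, here and below), Phlda3 at 4.09 ± 0.32 and the cell cycle inhibitor Cdkn1a at 3.48 ± 0.26. Of 12 endothelial genes 9 were lower in iHep than in adult liver, as adjusted over the list alone (adjusted p = 0.186 with an estimated correlation). The fetal liver and hepatoblast list held 5 genes higher and 1 lower of 13 in iHep against adult liver, as adjusted over the list alone (adjusted p = 0.84 with an estimated correlation), with the oncofetal genes Hmga2 at 6.28 ± 0.40 and Igf2bp3 at 4.98 ± 0.27, which was −0.67 on another probe set, taken when those shared between transcripts were left out.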
